A study of Mus musculus with 3 samples.

How the data were processed

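RNA of 3 mouse cell cultures was measured on Illumina bead arrays, 1 array for each of E3 epiblast stem cells, reverted E3R cells and CGR8 embryonic stem cells. Per the labels' protocols, 400 ng of total RNA was amplified with 12 h of in vitro transcription and labelled with Cy3. The same protocols state that epiblast stem cells were taken off their feeder layer with collagenase IV, whereas the other 2 cultures were harvested on the dish.

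For each array the authors deposited a probe summary intensity, its standard error over beads and a detection p-value for 25697 probes. The submitters' processing notes name BeadStudio, with no version. The deposited intensities are raw: their lowest values were 70.5, 66.5 and 69.8 on the epiblast, reverted and embryonic stem cell arrays, so that background had not been subtracted, and their quartiles differed between arrays. The authors also deposited a table of processed intensity values. Their column medians were 80, 80.9 and 80, no value lay below 8, and their ranks matched the raw intensities of the same array (Spearman rho 1.000 for each array over 12582, 12582 and 12584 probes), which places them on a linear scale. How they were normalized is not given in the sources used here, and they served only as an alternative. Probes without such a value (13115, 13115 and 13113, none of them detected) were set to the lowest value, 8, and undetected probes entered at floors of log2 3.81, 4.25 and 4.32, lower than those of the main values below.

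The raw intensities were normalized with limma 3.58.1 in R 4.3.3 by its neqc method. This fits the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Later steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9. The table that pairs probes with genes named 1 gene symbol for 23978 probes, none with several and left 1719 without a name. Symbols of 23962 probes were updated by gene identifier to those of a mouse gene table built on GRCm38.p6, which also gave the chromosome and the neighbours of each gene and from which no coordinates are reported. This gave 16593 genes, of which 4777 had several probes; such a gene takes the probe with the highest mean signal over the 3 arrays.

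A probe counted as detected at a detection p-value under 0.01. A difference between 2 arrays was computed for genes detected on at least 1 of them. Where the dimmer array did not detect the probe, it entered at the lowest normalized signal among detected probes of that array (log2 4.87, 5.06 and 5.10) or at its own signal if higher, and the difference is written as "at least". A gene detected on only 1 of the 2 arrays could thus only be higher there, and had no value where its bound left no difference. Genes were counted as higher or lower at 2-fold or more. With 1 array per group no test across samples exists, and all counts describe these arrays. The standard error over beads was carried to the log2 scale; its median over detected probes was 0.10, 0.09 and 0.09 on the 3 arrays. It leaves out variation between cultures, RNA extracts and arrays.

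Before the data were examined, 26 gene lists with 557 entries were written down, and 492 entries matched a gene on the array. The lists covered naive, primed and shared pluripotency, germ layers and other cell types (primitive streak and definitive endoderm, neuroectoderm, trophoblast, extraembryonic endoderm, germ cells, mesenchyme, epithelium, fibroblasts of the feeder layer, endothelium and blood, and the 2-cell-like state), signalling targets (FGF-ERK, LIF-STAT3, Wnt, Nodal-Activin), metabolism, DNA methylation, imprinting, MHC and interferon response, stress, Y-linked genes with Xist, and reference genes. A list's median is given where at least 3 members were measured; the 2-cell-like list had 1 measured member and the endothelial and blood list 2, so neither has one. Each median was set against medians of 10000 random lists of the same size matched on mean signal. This position describes the arrays and is not a test.

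Genes named in the text were chosen by a rule fixed in advance: in each comparison the 10 largest differences in either direction among detected genes, up to 4 measured members of each list with the largest differences, and 17 markers whatever their value. The marker T was not analysed here. Predicted genes and near-identical families are named only among the 10 largest. Shares carry exact Clopper-Pearson 95% intervals over genes, which cover counting only. The position of reverted cells between both references and the sharing of differences were set against 1000 simulated arrays that differed by bead error alone.

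Alternatives fixed in advance were no background correction, a normexp offset of 50, scaling to a common median, the authors' processed values, detection at a p-value under 0.05, detection on every array compared, a 3-fold threshold, the mean of a gene's probes, and leaving out the fibroblast, endoderm and mesenchymal lists. Undetected values as measured were fixed in advance for list medians and added later for counts and shares. Leaving out the run of genes on chromosome 14 was added after seeing the data. The run was found by medians of 25 neighbouring genes and bounded where they stayed above a log2 difference of 0.4, and was compared with 1000 shuffles of the gene order. The window and this level were set after the run had been seen, and tests over the whole chromosome, made first, were replaced by tests of the run.

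The scripts were tested on simulated data made from the reverted array, for the comparison of reverted with epiblast stem cells. Genes given a set fold were drawn from detected genes well above background, so dim genes were not tested. Of 50 genes changed 1.5-fold, 0% were counted at 2-fold; of 50 changed 2-fold, 24.0%; of 50 changed 3-fold, 88.0%; and of 50 changed 8-fold, 100%. None of 6856 unchanged genes was counted. Unchanged genes differed by bead error alone, which puts hardly any gene past 2-fold. The simulation left out variation between cultures, RNA extracts and arrays, so this gives no rate of false counts. Of 200 random lists of unchanged genes, 3.0% fell outside the middle 95% of matched lists. A simulated run of 39 genes raised by 0.8 on the log2 scale was found with all its genes, in a region of 41 genes. An earlier rule, which took every gene of the windows above that level, overstated the simulated run and was replaced by the middle genes of those windows after this test. The fold of Emb and 1 share under the authors' values are printed with 1 digit more than other folds and shares because their 3-digit forms equal settings typed in the scripts.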

Results

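Gene expression was profiled in 3 mouse pluripotent cell cultures with 1 bead array each. The first culture was the E3 line of epiblast stem cells, which derive from the post-implantation epiblast and have a hybrid genetic background. It was grown on inactivated mouse embryonic fibroblast feeders with 5 ng/ml of the growth factor FGF2. The second culture, E3R, consisted of epiblast stem cells of the same line that had been reverted to a state like that of embryonic stem cells. The third was the embryonic stem cell line CGR8. Reverted and embryonic stem cells shared a gelatin substrate and a medium with 1 µM of the MEK inhibitor PD0325901, 3 µM of the GSK3 inhibitor CHIR99021 and 1000 U of leukaemia inhibitory factor (LIF). Each group had 1 array, so no difference between groups has a replicate check and no p-value is given. Differences are stated as sizes, and the bead standard error beside a log2 difference covers the beads of a probe on these arrays only. The size of a fold also depends on the background model: of 174 recomputed differences of 2-fold or more, 104 had a fold over 1.5 times smaller without background correction and 86 with an offset of 50.

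Each array carried 25697 probes. On the epiblast stem cell array 10791 probes (42.0%) were detected above negative controls, against 9994 (38.9%) on the reverted array and 9860 (38.4%) on the embryonic stem cell array. Median raw signals were 89.2, 85.3 and 92.9 in that order. The probes used for 8224 genes were detected on at least 1 array, and those for 6105 genes on all 3.

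The first comparison set reverted against unreverted epiblast stem cells of the same line and asked which genes differed after reversion. Genes of naive pluripotency, the state of embryonic stem cells, were far higher in reverted cells. Esrrb, an orphan nuclear receptor of the embryonic stem cell network, was 86.5-fold higher (log2 difference 6.44, bead standard error 0.13; 5.11 without background correction and 5.43 with an offset of 50). Zfp42, also called Rex1, was 69.8-fold higher (6.13, bead standard error 0.18). Egr1, an immediate early transcription factor downstream of ERK signalling, was at least 121-fold lower in reverted cells. Fgf5, a growth factor of the primed epiblast, was at least 11.4-fold lower. Of 7726 genes with a value, 981 were at least 2-fold higher in reverted cells and 957 at least 2-fold lower, together 25.1%.

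Among the largest differences upward, Laptm5, a lysosomal membrane protein gene, was at least 155-fold higher in reverted cells (log2 7.27, but 5.59 without background correction and 5.96 with the offset of 50). Ooep, an oocyte-expressed gene, was 142-fold higher (log2 7.15, but 5.65 without background correction). As the value of Laptm5 is a lower bound, these genes cannot be ranked. Rhox5, an X-linked homeobox gene, was 90.0-fold higher. Xlr4a was at least 78.1-fold higher, Gstp2 at least 64.2-fold and Aard at least 62.4-fold. Downward, Trh, which encodes the precursor of thyrotropin-releasing hormone, was 66.3-fold lower than in epiblast stem cells. The sulfotransferase gene Chst1 was at least 38.8-fold lower and the carbonic anhydrase gene Car14 27.3-fold lower. Rbmx was at least 20.9-fold lower, Emb 17.5-fold and the chemokine gene Cxcl12 14.1-fold lower. Rbmx went from −4.39 on the log2 scale to −2.94 without background correction, and Cxcl12 from −3.82 to −2.45, and to −1.81 with the mean of its probes.

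Within the naive pluripotency list, 22 of 25 measured genes were at least 2-fold higher in reverted cells, with a median log2 difference of 3.18. Besides Ooep, Esrrb and Zfp42, these included Dppa5a at 56.9-fold and the adhesion gene Pecam1 at 12.9-fold. Eras was the single member at least 2-fold lower, at 3.76-fold, and is named here after its value was seen. In the primed pluripotency list, 13 of 22 measured genes were at least 2-fold lower and 1 was at least 2-fold higher, with a median of −1.57. The tight junction gene Cldn6 was 20.8-fold lower, the kinase gene Pim2 at least 14.8-fold, the Nodal antagonist gene Lefty1 12.3-fold and the homeobox gene Otx2 7.55-fold. With the mean of its probes Pim2 went from −3.89 on the log2 scale to −2.53. Medians of 10000 random lists matched on size and signal had a middle 95% from −0.41 to 0.46 for the naive list and from −0.43 to 0.40 for the primed list.

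Pluripotency genes shared by both states differed in both directions. Of 14 measured, 3 were at least 2-fold higher in reverted cells, 3 at least 2-fold lower and 8 within 2-fold. Pou5f1, which encodes Oct4, differed by only 1.44-fold, being lower in reverted cells, and Nanog was 1.96-fold higher. Sox2 was 3.29-fold higher (log2 difference 1.72, but 0.85 with the mean of its 2 probes, which is under 2-fold). Dppa4 was 58.6-fold higher (log2 5.87, but 4.40 with the mean of its probes). The de novo DNA methyltransferase gene Dnmt3b was 5.78-fold lower and Utf1 4.42-fold lower.

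Of 25 matched germ cell genes, only 10 had a value. These were higher in reverted cells, with 7 of 10 past 2-fold and a median log2 difference of 1.84 (0.86 without background correction). Members detected in reverted cells alone, given below as "at least", could only count as higher. Tuba3a, a testis tubulin gene, was at least 58.9-fold higher and the RNA-binding protein gene Dazl at least 13.0-fold. Dppa3 was 4.19-fold higher, and Stra8, a gene of meiotic entry, at least 2.20-fold higher, although under 2-fold without background correction (log2 0.45) and with an offset of 50 in the background model (0.57). Among DNA methylation genes, 5 of 9 measured were at least 2-fold higher and 2 at least 2-fold lower, with a median of 1.16. Dnmt3l, a cofactor of de novo methylation, was 55.2-fold higher and the maintenance methyltransferase gene Dnmt1 2.72-fold higher, opposite to Dnmt3b.

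Among targets of the pathways that the media components act on, the FGF-ERK and LIF-STAT3 lists lay outside the range of random lists and the Wnt list inside it. Of 17 measured FGF-ERK response genes, 6 were at least 2-fold lower in reverted cells and 1 at least 2-fold higher, with a median of −0.55. Fos was 10.7-fold lower, the phosphatase gene Dusp4 at least 6.16-fold and the cyclin gene Ccnd1 2.40-fold. Medium, feeder layer and harvest with collagenase IV differed together between these cultures, so no effect of the medium can be singled out. Of 15 measured LIF-STAT3 targets, 6 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.59. The transcription factor gene Klf5 was 19.8-fold higher, Gbx2 18.1-fold and the feedback inhibitor gene Socs3 7.44-fold, while Klf4 was at least 9.29-fold higher. Among 7 measured Wnt targets, 1 gene was at least 2-fold higher, Notum at 5.31-fold or more, and 1 at least 2-fold lower, Ccnd1, and the median was −0.03. For 12 measured Nodal-Activin targets the median was −0.54, within the random range.

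Epithelial genes were lower in reverted cells: 8 of 15 measured genes were past 2-fold and 0 were 2-fold higher, with a median of −1.30. The splicing regulator gene Esrp1 was 15.2-fold lower, the keratin gene Krt8 10.3-fold and Krt18 at least 8.06-fold. The mesenchymal list had a median of 0.77 over 6 measured genes. Tgfbi was 8.14-fold higher and Vim 2.38-fold higher, whereas Mmp2 was 2.89-fold lower. The fibroblast genes were listed to mark the feeder layer, which only epiblast stem cells had. Of these, 8 of 16 measured were at least 2-fold lower in reverted cells and 0 were 2-fold higher. Members were not particular to feeders. Ccn2 had log2 signals of 8.78 in reverted and 9.65 in embryonic stem cells, and Col5a1 was higher in embryonic (7.81) than in epiblast stem cells (6.14). The surface protein gene Thy1 was at least 6.38-fold lower, Ccn1 at least 4.84-fold and the proteoglycan gene Bgn at least 3.26-fold, the last under 2-fold without background correction (log2 −0.81) and with the offset of 50 (−0.98). The fibroblast median of −1.03 lay between those of the epithelial and the MHC lists, which were likewise higher on the array of the feeder culture.

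Several other groups lay outside the range of random lists. Of 14 measured cholesterol synthesis genes, 7 were at least 2-fold lower in reverted cells and 0 were 2-fold higher, with a median of −0.92. Dhcr7 was 5.07-fold lower, Mvd 4.69-fold and Lss 4.55-fold. In the list of MHC class I and interferon response genes, 5 of 11 measured were at least 2-fold lower (median −0.87), including the GTPase gene Irgm1 at 3.09-fold and B2m at 2.34-fold (log2 −0.98, under 2-fold, without background correction). Of 16 measured imprinted genes, 5 were at least 2-fold lower and 1 at least 2-fold higher (median −0.66), with Grb10 at 9.74-fold, the cell cycle inhibitor gene Cdkn1c at 5.64-fold and Gnas at 4.26-fold. Trophoblast genes had a median of 0.84 over 5 measured genes, 2 at least 2-fold higher and 1 lower, of which Tfap2c, also a germline factor, was 30.9-fold higher. The bootstrap intervals of the trophoblast, mesenchymal and DNA methylation medians spanned 0.

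The other lists with enough measured genes stayed inside that range. Extraembryonic endoderm genes had a median of 0.45, with 3 genes at least 2-fold higher and 1 lower: the laminin gene Lama1 was 14.6-fold, Gata6 3.73-fold and Dab2 2.17-fold higher and Col4a1 2.34-fold lower, the last 2 under 2-fold without background correction and with the offset of 50. Dab2 was also under 2-fold with the mean of its probes (log2 0.59). Primitive streak and definitive endoderm genes had a median of −0.08 over 6 measured genes, and Fgf8 was at least 7.67-fold lower. For neuroectoderm the median was 0.28 over 4 genes. Glycolysis genes had a median of −0.25, with Ldha 2.66-fold lower, and 19 of 21 oxidative phosphorylation genes (median −0.05) were within 2-fold. Among stress response genes (median 0.32) the small heat shock protein gene Hspb1 was 17.3-fold higher and Chac1 2.92-fold lower. Of 11 reference genes (median −0.25), 9 were within 2-fold, and Hprt was 2.89-fold lower.

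Across genes, the log2 signals of reverted and epiblast stem cells correlated with a Pearson r of 0.869 over 8224 genes, which are not independent replicates. Without background correction 554 genes were higher and 470 lower, and with an offset of 50 in the background model 633 were higher and 561 lower, since both choices shrink differences of dim genes.

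**Figure D1:**
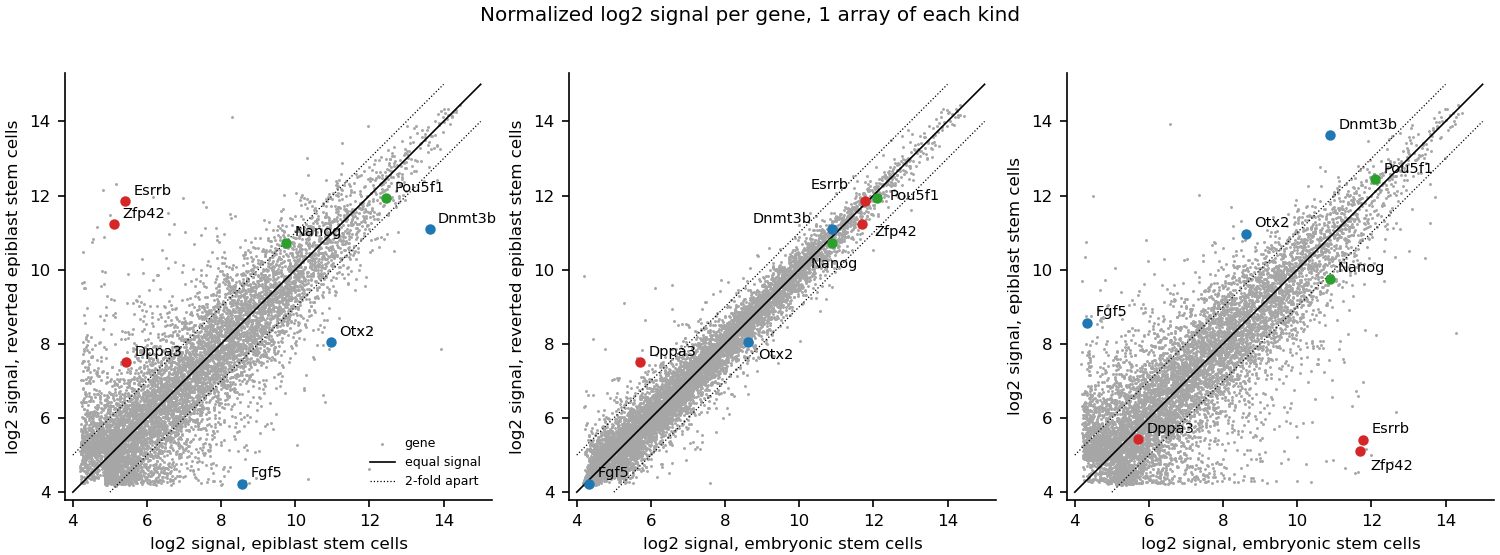
Normalized log2 signal of each gene detected on at least 1 array, 1 point per gene and 1 array per kind of cell, with reverted against epiblast stem cells on the left, reverted against embryonic stem cells in the middle and epiblast against embryonic stem cells on the right. Named markers are coloured red for naive, blue for primed and green for shared pluripotency genes; Esrrb and Zfp42 leave the diagonal on the left and on the right and lie near it in the middle, where r was 0.977.

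The second comparison set reverted cells against embryonic stem cells in the same medium and asked what still set the reverted line apart. Few genes did: 132 were at least 2-fold higher in reverted cells and 112 at least 2-fold lower, together 3.35% of 7286 genes with a value. Esrrb differed by 1.06-fold (log2 difference 0.08, bead standard error 0.06), Sox2 by 1.02-fold, Nanog by 1.11-fold, Pou5f1 by 1.13-fold and Zfp42 by 1.36-fold. Dppa3, a gene of early germ cells and naive cells, was 3.46-fold higher in reverted cells. The endodermal adaptor gene Dab2 was 3.49-fold lower and the type IV collagen gene Col4a1 3.10-fold lower.

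Of the 10 largest differences upward, 8 belonged to genes that were at least 2-fold above embryonic stem cells in epiblast stem cells too. Both differences use the same embryonic stem cell array, so a deviation of that array alone would also give this. Thumpd1, an adaptor of tRNA acetylation, was at least 26.7-fold higher in reverted cells, with log2 signals of 9.68 in epiblast and 9.84 in reverted cells. Atf4, a transcription factor of the integrated stress response, was 10.4-fold higher. The proteasome subunit genes Psmd8 and Psmb5 were 8.16-fold and 5.23-fold higher, the COP9 signalosome gene Cops8 at least 8.10-fold and the mitochondrial import gene Tomm22 6.96-fold. Rgcc, a cell cycle regulator gene, at 14.2-fold and Nod1 at 6.73-fold or more were the other 2, highest in reverted cells alone. Eno2 was 4.21-fold and Nfatc4 4.02-fold higher. Downward, Mid1 was at least 5.78-fold lower in reverted cells, Parm1 4.41-fold, Fam177a 4.40-fold and the alcohol dehydrogenase gene Adh1 4.09-fold. The predicted gene 1700016D06Rik was 4.07-fold lower, Susd4 4.05-fold, Krt8 3.98-fold, Emp1 3.87-fold, Tmem64 3.87-fold and Slc11a1 3.85-fold. Of the 16 genes at least 4-fold apart, 12 had a single probe.

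Of 27 measured naive pluripotency genes, 25 were within 2-fold, with Dppa3 higher and Spic at least 2.33-fold lower, and the median log2 difference was 0.01. Of 16 measured primed genes, 13 were within 2-fold and the median was 0.11. Lefty1 was 2.05-fold higher in reverted cells, while Krt8 and Krt18 (at least 2.37-fold) were lower. Otx2 was 1.47-fold lower, Dnmt3b 1.16-fold higher, and Fgf5 was detected in neither. The shared pluripotency list had a median of 0.23, above the middle 95% of its random lists, which ended at 0.21; L1td1 was 3.02-fold higher and Tdgf1 2.06-fold lower (log2 difference −0.56, under 2-fold, with the mean of its probes). Of 10 measured extraembryonic endoderm genes, 4 were at least 2-fold lower, Gata6 at 2.47-fold and Col4a2 at 2.43-fold besides Dab2 and Col4a1, and the median was −0.83 against a random range from −0.25 to 0.25.

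Several other lists had medians outside their random range, with most members inside 2-fold. Glycolysis genes had a median of −0.45, with 16 of 18 within 2-fold; Pgk1 was 2.04-fold lower and Eno2 higher. Cholesterol synthesis genes had a median of −0.55, with 13 of 14 within 2-fold and Stard4 3.08-fold lower. Medians of the FGF-ERK, epithelial, germ cell and Nodal-Activin lists were −0.30, −0.33, −0.33 and −0.25, each below its random range, but the bootstrap intervals of all but the epithelial list spanned 0, and both germ cell genes past 2-fold were higher. Ier3 was 2.84-fold lower, while Ccnd1 was 3.20-fold higher in reverted cells. Wnt targets had a median of 0.37 over 7 genes, above their range, with Notum 2.57-fold higher. Their median was 0.14 without background correction and 0.18 with the offset of 50. For fibroblast genes the median was 0.00 over 10 measured genes, with Serpinf1 at least 3.06-fold higher and Col5a1 2.20-fold lower. LIF-STAT3 targets had a median of −0.08, MHC and interferon genes 0.28, imprinted genes −0.02 and DNA methylation genes −0.24, all inside their ranges. In total 9 of 23 lists lay outside the middle 95% of their random lists, against 13 of 24 in the first comparison. Some lists share members, such as Krt8 in the primed and the epithelial list, so the lists are not independent.

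**Figure D2:**
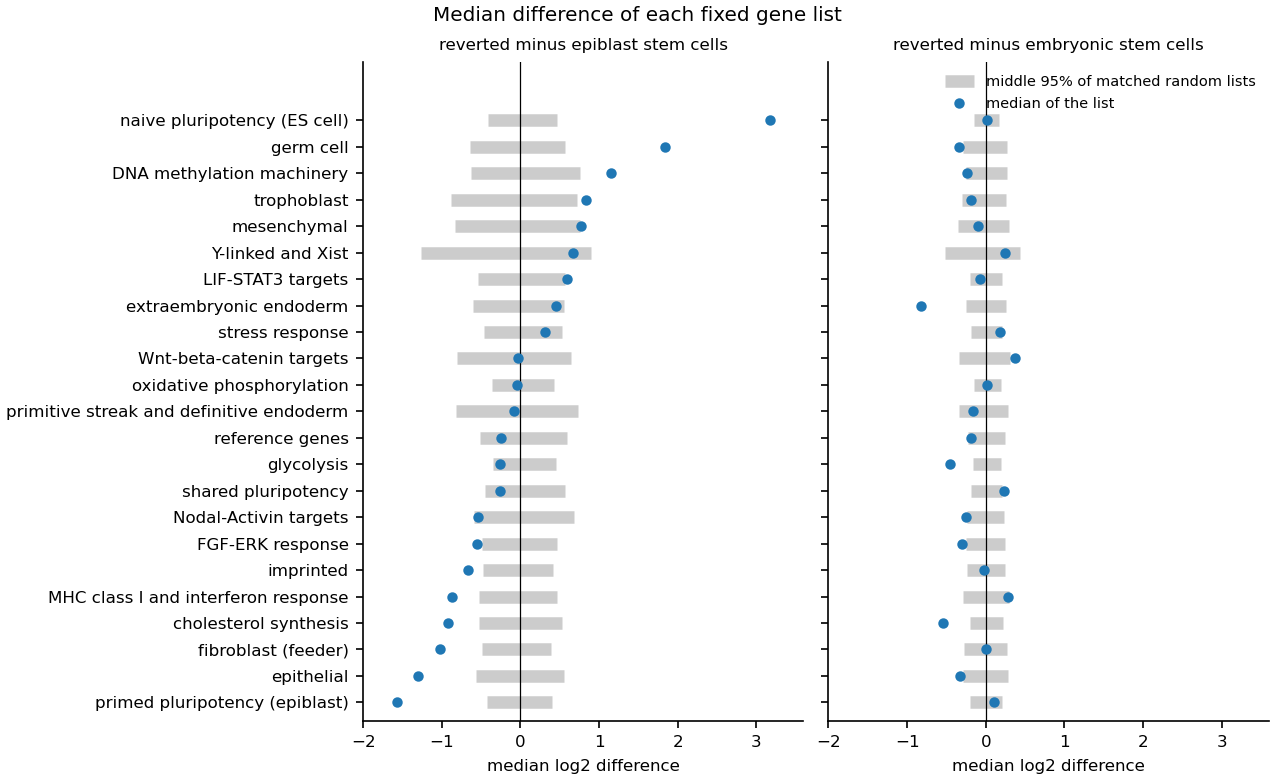
Median log2 difference of each of 23 gene lists (points) with the middle 95% of medians of matched random lists (grey bars), for reverted minus epiblast stem cells on the left and reverted minus embryonic stem cells on the right, 1 array per kind of cell. Medians on the left run from −1.57 for primed to 3.18 for naive pluripotency, and those on the right from −0.83 for extraembryonic endoderm to 0.37 for Wnt targets.

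A run of neighbouring genes on chromosome 14, found after the values were seen, held 25 of the 132 genes higher in reverted cells and 0 of the 112 lower ones. It reached from Armh4 to Med4 in chromosomal order and held 90 genes detected in both cultures. Of these, 79 (87.8%, exact 95% interval 79.2 to 93.7) were higher in reverted than in embryonic stem cells, with a median log2 difference of 0.61. The other 119 genes of the chromosome had a median of 0.01. The run was bounded by these same differences, which raises the share, its interval, the run's median and its contrast with the other genes. Epiblast stem cells exceeded embryonic stem cells over the same run by a median of 0.74, and reverted and epiblast stem cells differed over it by a median of −0.04. The median of 0.74 uses the same embryonic stem cell array, so it is not a separate check. Psmb5, Nfatc4, the DNA repair gene Apex1 (3.53-fold), the RNA methyltransferase gene Mettl3 (2.94-fold) and the arginine methyltransferase gene Prmt5 (2.57-fold) lay in the run; the last 3 are named after their values were seen.

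**Figure D3:**
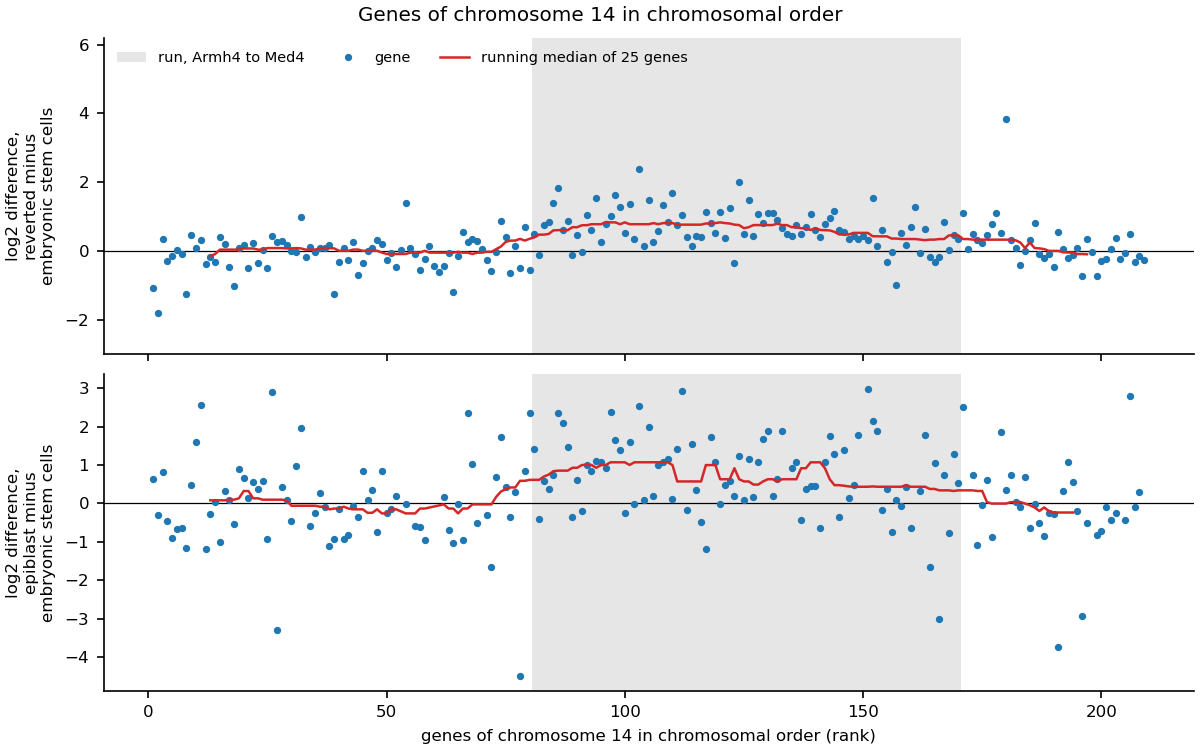
Log2 difference of each gene of chromosome 14 detected on both arrays, by rank in chromosomal order, for reverted minus embryonic stem cells (top) and epiblast minus embryonic stem cells (bottom), with the running median of 25 genes in red and the run in grey. Over the grey run, bounded by the values of the upper panel, the medians were 0.61 and 0.74, against 0.01 and −0.06 over the rest of the chromosome.

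Reverted and embryonic stem cells correlated with an r of 0.977 across the 8224 genes. Without background correction 38 genes were higher and 37 lower, with an offset of 50 these were 50 and 48, and with the authors' own normalized values, whose floors for undetected probes are lower, 219 and 211. Of the genes named in this comparison, Spic, Krt18, Lefty1, Col4a2, Serpinf1, Col5a1, Notum, Pgk1 and Tdgf1 were under 2-fold without background correction and with the offset of 50. Line, genetic background and history differ together between these cultures.

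The third comparison set epiblast against embryonic stem cells, which differ in line, genetic background and culture. Genes of the naive state were among those lower in epiblast stem cells, and genes of the primed epiblast, epithelium and FGF-ERK response were among those higher. Trh was 163-fold higher in epiblast stem cells (log2 difference 7.35, bead standard error 0.13), Egr1 at least 118-fold higher and Lefty1 25.2-fold higher. Esrrb was 81.9-fold lower (−6.36, bead standard error 0.13), Zfp42 95.3-fold lower and Dnmt3l 89.9-fold lower. In all, 1067 of 7698 genes with a value were at least 2-fold higher in epiblast stem cells and 1035 at least 2-fold lower, together 27.3%.

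Other large differences upward were Emb at least 49.98-fold, Chst1 at least 37.8-fold, Car14 at least 30.9-fold, Cldn6 29.1-fold and the serine protease gene Klk8 at least 24.7-fold. Thumpd1 and Rbmx were at least 23.9-fold and 20.4-fold higher. Downward, Laptm5 was at least 206-fold lower in epiblast stem cells, Rhox5 128-fold, Aard at least 110-fold, Ooep 105-fold, Tuba3a at least 102-fold, Xlr4a at least 85.8-fold and the water channel gene Aqp3 at least 69.0-fold.

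In the naive list 22 of 27 measured genes were at least 2-fold lower in epiblast stem cells, with a median of −3.11, and in the primed list 13 of 21 were at least 2-fold higher, with a median of 1.76. Fgf5 was at least 11.1-fold higher, Pou3f1 12.4-fold and Otx2 5.13-fold. Pou5f1 was 1.28-fold higher and Nanog 2.17-fold lower. LIF-STAT3 targets had a median of −0.84 and germ cell genes of −1.56, with Dazl at least 18.2-fold lower. DNA methylation genes had a median of −1.27, with a bootstrap interval that spans 0, and Dnmt3b was 6.68-fold higher. Extraembryonic endoderm genes had a median of −0.60, with 3 of 10 measured at least 2-fold lower and 7 within 2-fold. Lama1 was 28.9-fold lower and Gata6 9.21-fold lower. Medians above the random range were those of epithelial (0.90; 7 of 15 at least 2-fold higher, 1 lower), imprinted (0.60; 6 of 16 higher, 2 lower), MHC and interferon (0.77; 5 of 11 higher, 0 lower) and FGF-ERK response genes (0.55; 5 of 16 higher, 2 lower, with a bootstrap interval that spans 0). Esrp1 was at least 15.2-fold and Grb10 11.3-fold higher. Of 17 measured fibroblast genes, 9 were at least 2-fold higher on the epiblast stem cell array, with a median of 1.14 and Thy1 at least 6.21-fold higher. Eomes and Sox17, markers of streak and endoderm, were at or near background: Eomes was detected in embryonic stem cells only, and neither Sox17 nor Cer1 was detected on any array.

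The r across genes was 0.853. Without background correction 538 genes were higher and 573 lower, and with an offset of 50 these were 634 and 673.

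The last comparison asked how near the reverted cells lay to either reference. Of the 2102 genes at least 2-fold apart between epiblast and embryonic stem cells, 1870 (89.0%, exact 95% interval 87.5 to 90.3) lay nearer the embryonic stem cell signal in reverted cells. Among genes higher in epiblast stem cells the share was 89.5%, and among those lower 88.4%. The median gene lay 90.0% of the way from the epiblast to the embryonic stem cell log2 signal. Laptm5, Esrrb and Zfp42 were on the embryonic side, with log2 signals of 12.14, 11.85 and 11.23 in reverted and 12.56, 11.77 and 11.68 in embryonic stem cells. Thumpd1, Atf4 and Psmd8 were on the epiblast side. Reverted and embryonic stem cells also shared medium, substrate and harvest, in all of which epiblast stem cells differed. No array here held unreverted epiblast stem cells in that medium, so an effect of culture cannot be told apart from reversion. Simulated reverted arrays copied either reference array with bead error and left out variation between cultures. In the median simulation, copies of the epiblast stem cell array put 0.05% of the genes nearer the embryonic side. Copies of the embryonic stem cell array put 99.95% there.

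Reverted and embryonic stem cells shared 770 genes at least 2-fold higher than in epiblast stem cells, of 975 and 1025 such genes among 7463 with a value in both comparisons; independent lists would share 134. They shared 770 genes at least 2-fold lower, of 957 and 1067, where independent lists would share 137, and 1 gene went in opposite directions. Both comparisons use the same epiblast stem cell array, so part of the excess may come from that array. Part may also come from the medium, substrate and harvest that reverted and embryonic stem cells shared. Simulations of unchanged arrays with bead error alone shared at most 1 gene, but bead error by itself puts hardly any gene past 2-fold and leaves out variation between cultures.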

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

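Both tests of variants under probes, the look at collagen probes, the test of the fibroblast list against lists of the same signal in each setting and the bootstrap margins on the tests of normalization and of the cells' own expression were chosen after values were seen; the other tests in this part were set before.

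Probes without a gene name, which no comparison above uses, carried signal: 685 of 1719 were detected on at least 1 array. Between reverted and epiblast stem cells 73 of these probes were at least 2-fold higher and 77 at least 2-fold lower, and between reverted and embryonic stem cells 15 were higher and 4 lower. Probe ILMN_2737090 was 119-fold higher in reverted than in epiblast stem cells, a difference on the scale of Ooep and Laptm5. Probe ILMN_3159435 was 39.7-fold lower in reverted than in embryonic stem cells.

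Fibroblast-list genes were higher on the epiblast stem cell array, the only one from a feeder culture, than on both others. The smaller of the 2 medians was 1.03, with 12 of 16 genes higher than in reverted and 13 of 17 higher than in embryonic stem cells. These values reached the sizes set in advance for RNA from feeder fibroblasts. However, 9 list members were detected on the epiblast stem cell array alone and could only count as higher. That raises the shares and medians, so reaching those sizes does not decide for feeder RNA. Normalization between arrays is argued against by the lowest median over the scaling and background alternatives, 0.55. It was above the bound set in advance but had a bootstrap margin down to 0.14. The list also lay above the middle 95% of lists of the same signal in 10 of 10 settings and comparisons. Normalization would move such lists alike. Those lists were not matched on which arrays detected a gene, so the detection rule may add to this. Against feeder RNA, all 4 probes of Col1a1, Col1a2 and Col3a1, abundant collagens of fibroblasts named here after their values were seen, were undetected there, but no array here shows that those probes respond. Expression by the stem cells themselves was tested by endoderm and streak lists, whose larger median was 0.078, under the bound set in advance, but with members going both ways and a margin up to 2.40. Feeder RNA and the cells' own expression cannot be told apart on these arrays.

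Genes at least 2-fold apart between reverted and embryonic stem cells number 244. A variant that weakens 1 probe is argued against for genes with further probes: 69.0% of 71 other probes differed the same way by 1.5-fold or more (exact 95% interval 56.9 to 79.5), against 56.9% of 792 between reverted and epiblast stem cells, which share a genome. For the 157 genes with a single probe it stays open: the epiblast signal was nearer the reverted one in 71.3%, between the bounds for and against. A difference between the cell lines may contribute. Over all 244 genes the epiblast stem cell signal lay nearer the reverted one in 70.5% (exact 95% interval 64.3 to 76.1). Remaining epiblast expression would also give this. A deviation of the 1 embryonic stem cell array, which enters the choice of these genes, would give it too. The primed list alone did not decide on remaining epiblast expression, with its median at the 84.3rd percentile of random lists.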

How the results depend on the processing

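All alternatives were fixed before the data were examined except leaving out the chromosome 14 run and, for counts and shares, undetected values as measured. No named 2-fold difference and no list median outside its random range changed direction in any alternative run. Of 497 recomputed list medians 486 stayed within their bootstrap interval, 11 moved and 0 reversed, and of 1218 recomputed 2-fold differences of named genes 1176 stayed at 2-fold or more. The lost ones were mostly dim genes without background correction (18) or with an offset of 50 (17); for example Stra8 in reverted minus epiblast stem cells went to 0.45 and 0.57, and Bgn to −0.81 and −0.98. With the mean of a gene's probes 4 were lost, among them Sox2 in reverted minus epiblast stem cells, from 1.72 to 0.85, and Tdgf1 in reverted minus embryonic stem cells, at −0.56. Counts stayed within 1.5 times the main ones, and correlations and shares within their 95% intervals, under median scaling, without the fibroblast, endoderm and mesenchymal lists and without the chromosome 14 run. The fold of 174 named differences was over 1.5 times smaller for 104 without background correction (median 74.6% of the log2 difference left), 86 with an offset of 50 (80.9%) and 16 with the mean of a gene's probes, and over 1.5 times larger for 64 with the authors' values and 19 with undetected values as measured. For counts, correlations, shares and list medians that moved, the values follow in the order reverted against epiblast, reverted against embryonic and epiblast against embryonic stem cells.

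Without background correction the counts higher and lower were 554 and 470, 38 and 37, and 538 and 573, and r was 0.889, 0.982 and 0.877. The share nearer the embryonic side was 91.2%, and 92.0% for genes lower in epiblast stem cells. The naive median was 2.03 (reverted minus epiblast) and −2.08 (epiblast minus embryonic), that of germ cell genes 0.86 (reverted minus epiblast), of Wnt targets 0.14 (reverted minus embryonic) and of LIF-STAT3 targets −0.44 (epiblast minus embryonic). With an offset of 50 the counts were 633 and 561, 50 and 48, and 634 and 673, r was 0.885, 0.981 and 0.873, the shares were 91.1% and 91.4%, the naive median was 2.14 and the Wnt median 0.18. Uncorrected background or a larger offset stays in every signal, which by construction shrinks differences of dim genes most. The offset of 50 also came with a background fit that did not use the detection p-values.

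With the authors' processed values, where undetected probes entered at lower floors, r was 0.839, 0.967 and 0.819, and 219 genes were higher and 211 lower in reverted than embryonic stem cells. The share nearer the embryonic side was 86.1%, 87.2% for genes higher and 85.01% for genes lower in epiblast stem cells. The median of Y-linked genes and Xist was 1.28 (reverted minus epiblast) and −0.91 (epiblast minus embryonic), and that of trophoblast genes −0.35 (reverted minus embryonic); the cause was not tested. With undetected values as measured the trophoblast median was −0.37. Detection at a p-value under 0.05 gave r of 0.893, 0.980 and 0.880 over more genes. For reverted and embryonic stem cells r was 0.974 over genes detected on all 3 arrays and 0.975 with the mean of a gene's probes. The cause was not tested. At 3-fold, which counts fewer genes by construction, the counts were 427 and 332, 26 and 24, and 410 and 467, and the shares were 90.6% and, for genes lower in epiblast stem cells, 91.2%.

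Signal over background limits the dim end, where genes near the floor give bounds. A simulated 2-fold change, which lies exactly at the threshold, was counted in 24.0% of 50 genes, with a median log2 difference of 0.93. These genes lay well above background, so counting at the dim end was not tested. No paired analysis was possible because each group had 1 array, which also left no replicate to leave out.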

Other observations

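All tests of chromosome 14, their bounds and the limits of the run were chosen after its values were seen, and those of the run replaced earlier ones over the whole chromosome.

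Genes of the sex chromosomes were also looked at by themselves. Eif2s3y, a Y-linked gene, had log2 signals of 8.42, 8.42 and 8.45 in epiblast, reverted and embryonic stem cells, and Xist, the RNA of the inactive X chromosome, was not detected on any array. The list of Y-linked genes and Xist had a median of 0.67 for reverted minus epiblast and 0.24 for reverted minus embryonic stem cells over 3 measured genes. Genes of the X chromosome detected in both cultures had a median log2 difference of −0.34 between reverted and epiblast stem cells over 192 genes, the lowest of any chromosome. The 18 other chromosomes apart from chromosome 14 lay between −0.11 and 0.15. Against embryonic stem cells the X chromosome did not stand out, with 0.13 for epiblast and −0.05 for reverted minus embryonic stem cells, both inside the range of random gene sets. Rhox5 and Xlr4a, both X-linked, went the other way and were among the 10 largest differences upward in reverted cells.

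The run of genes on chromosome 14 from Armh4 to Med4, which sat higher in both E3-derived cultures than in embryonic stem cells, is open to several readings. Chance order is argued against: the highest median of 25 neighbouring genes was 0.84 for reverted and 1.07 for epiblast minus embryonic stem cells, above the highest of 1000 shuffles at 0.47 and 1.03, the latter by little. Sequence variants under single probes are not excluded. Of the genes 87.8% were higher, a share that the choice of the run raises. Even so, the lower end of its interval, 79.2%, fell short of the bound set for excluding them. A copy number difference between the lines may account for it. The median of 0.61 (bootstrap 95% interval 0.49 to 0.76) has about the size that a gain of 1 copy in the E3 line would give. Reverted and epiblast stem cells differed by −0.04. The size depends on the background model: the median was 0.43 without background correction and 0.48 with the offset of 50. It was 0.60 with median scaling and 0.65 with the authors' processed values. No DNA was measured, and the median rests on genes chosen for their run.

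The earlier tests over the whole of chromosome 14 read less clearly. Its median was 0.27 for reverted minus embryonic stem cells, above the highest of 10000 matched random gene sets at 0.13, as chromosome 8 also was with 0.11 against 0.09, but 0.30 for epiblast minus embryonic stem cells, below the highest at 0.32, so that chance was not excluded there. An earlier test that left out genes at least 2-fold apart removes the difference it tests and is not used. A copy number difference of the whole chromosome is argued against by 5 equal parts of it by gene order, which do not depend on the values: in 2 the median for reverted minus embryonic stem cells, 0.023 and −0.0044, had a bootstrap upper bound under 0.3, namely 0.10 and 0.14. In the parts from Osgep to Gm5801 and from Zmym5 to Rb1 the median was 0.80 and 0.55, and in the last part 0.08.

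Chromosome 13 held the highest run of 25 genes outside chromosome 14, in the neighbourhood of a histone gene cluster. Its median was 0.69 from Amph to H2ac7 for reverted minus embryonic stem cells. From Epdr1 to H3c4 it was 1.28 for epiblast minus embryonic stem cells, above the 1.07 of chromosome 14. Both lay above the highest of the shuffles, 0.47 and 1.03. Exceeding the shuffles is therefore not particular to chromosome 14 and does not tell why neighbouring genes differ alike.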
